A study of Mus musculus with 8 samples.

How the data were processed

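Total RNA from developing white adipose tissue of C57BL/6 mice was measured at 8 stages, 4 embryonic (e15.5, e16.5, e17.5 and e18.5) and 4 postnatal (P0, P2, P5 and P12). Each stage had 1 pooled sample on 1 array. The labels give at least 3 embryos per pool in 1 place and 4 in another. The depot is not given. The RNA was amplified, labelled with biotin and hybridized to Illumina MouseRef-8 BeadChips, which carry bead-bound probes for mouse transcripts, per the labels' protocols. Image processing and data extraction used BeadStudio, per the labels' protocols.

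The deposited values used here are the authors' processed log2 intensities, 1 column per sample, for 25697 probes. Their log base was read from the range, 6.66 to 15.10, and is not stated. The sorted values of the 8 deposited columns were equal to within 0.005, so every array had the same distribution, with a median of 6.99. Such values hide any change in total signal between stages. The background treatment, the normalization method and any added offset are not given in the sources used here. Log2 differences of dim probes are compressed towards the floor of about 6.7. A second deposited table of unnormalized signals and detection values was not used: its 16 per-sample columns carry numbers and chip positions that match no sample label. The background correction with control probes and the filter on detection values that had been planned were for that reason replaced. A probe was kept where its value reached 7.5 on at least 2 of the 8 arrays. This minimum was chosen after the distribution of values had been seen and before any test was run. On each array 8318 to 8324 of the 25697 probes reached 7.5.

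Probes were named from the platform annotation. Of the 25697 probes, 23978 had 1 gene symbol, 0 had several and 1719 are unnamed here. Where a gene had several probes, the probe with the highest mean over the 8 arrays was used, which left 18312 features. The filter left 7446 features for testing, of which 6934 were named genes and 512 unnamed probes. A mouse gene table updated no symbol and otherwise served to look up synonyms of list genes and to find neighbouring genes. No build is named for the values, so coordinates are left out.

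Tests used limma 3.58.1 in R 4.3.3, with moderated variances and Benjamini-Hochberg adjustment over the 7446 features at 0.05. The trend fit took stage order, 1 to 8, as a line and left 6 residual degrees of freedom. The birth fit compared the 4 embryonic with the 4 postnatal arrays. The curvature fit added an orthogonal quadratic term and left 5 residual degrees of freedom. A positive coefficient means that the middle stages lay above a straight line through the series, and a negative one below it. Genes past the threshold are counted as peaking (positive) or lowest in the middle (negative). A gene that only rises or only falls can pass as well, if its change is uneven. No stage was replicated. The spread in each fit is therefore the scatter of single pools around the fitted line or means, and a real change that does not follow the line counts as error. Differences between neighbouring stages have no replicate check, so genes were counted at a difference of 2-fold or more, with no p-value. A level below 7.5 was treated as near the floor, and a fold against such a level is given as at least the fold against 7.5.

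A set of 29 gene lists was fixed before the data were examined: 16 pathway or process lists, 12 lists of markers of cell types that such a dissection could hold, and 1 list of sex-linked transcripts. Lists with at least 3 tested members, 27 in all, were tested with camera at its preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. Lists share members; Nnat, for example, is in the adipocyte and the imprinted list, Cidea in the adipocyte and the brown fat list, and Dlk1 in the imprinted and the progenitor list. Genes named were chosen by a rule, also fixed before the data were examined. It takes the 12 largest rises and 12 largest falls past the threshold, up to 6 each way for birth, 5 each way for curvature, 3 each way for every step among genes at 7.5 or more at both stages, up to 4 per list by size of slope, and a fixed set of 16 adipose genes. Clone and model names were left out of the first 2 parts. Other list members are named as examples, chosen after their values were seen.

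The trend test was tested on simulated arrays with the real means and residual spread of the 7446 features and 50 changed features of each size. It called 32% of features with a slope of 0.1 log2 per stage, 76% at 0.2, 90% at 0.4 and 100% at 0.8. Of its 155 calls, 3.87% were unchanged features. The features were simulated independently of each other, so this share does not describe calls where a single pool moves many genes together. The birth test, simulated with the spread around the period means, called 22% of features with a difference of 0.5 log2, 68% at 1, 90% at 2 and 100% at 4. The changed features were drawn at random, with a median SD of 0.21 to 0.24 log2, so these shares do not describe genes that vary more within a period. Alternatives covered the filter, variance model, array weights, muscle and epidermal marker means as covariates, time in days, single probes, each stage left out in turn and other set tests. Alternatives on the minimum, on subtracting the lowest value, on centring, and without pairs of arrays were chosen after seeing the data.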

Results

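Gene expression was followed through the formation of mouse adipose tissue, from e15.5 in the embryo to postnatal day 12. The 8 arrays, 1 per stage, shared a median of 6.99 on the log2 scale, and between 8318 and 8324 probes reached 7.5 on each. No stage had a replicate, so errors below are standard errors of fitted slopes or differences. Correlations between neighbouring stages over all probes ran from 0.966 (e15.5 with e16.5) to 0.985 (P5 with P12), across genes that are not independent replicates. The first principal component held 57.9% of the variance and ordered the arrays from e15.5 at -52.1 to P12 at 41.1. The P0 array lay at 0.38, below e18.5 at 9.28 and P2 at 12.1.

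The first question was which transcripts changed steadily with stage. Several of the largest rises were in genes of the adipocyte. Lep, which encodes the hormone leptin, rose by 0.98 log2 per stage (SE 0.13, adjusted p = 0.00177, probe ILMN_2695964), from 6.98 at e15.5 to 13.29 at P12, at least 55.5-fold. Plin4, a lipid droplet coat protein, rose by 0.91 per stage (SE 0.15, adjusted p = 0.00333), and Pnpla2, the triglyceride lipase, by 0.80 (SE 0.17, adjusted p = 0.00782). The preadipocyte factor Dlk1 fell by 0.88 per stage (SE 0.18, adjusted p = 0.00709, probe ILMN_1244618), from 14.03 to 7.32, at least 92.6-fold. Of 7446 features, 1363 rose and 1542 fell in limma's trend fit, and 44 rose and 18 fell by 0.5 log2 or more per stage. Without the P12 array 891 rose and 999 fell. Without both P5 and P12, chosen after seeing the data, 563 rose and 529 fell.

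The other large rises included Sncg (0.96 per stage), Ces1d, a carboxylesterase (0.93), Tmem45b (0.92), Lrg1 (0.80) and Scd1, the stearoyl-CoA desaturase (0.79). Ces1d was 7.45 at e15.5 and 13.83 at P12, at least 80.4-fold higher. Several of the leading genes were not gradual. Sncg stood between 7.72 and 8.86 through P0 and at 12.89 or more from P2. The imprinted gene Nnat went from 8.01 at P0 to 11.85 at P2, and Retnla, a resistin-like protein, from 7.67 at P2 to 11.99 at P5. The large falls included the growth factors Ptn, which fell by 0.69 per stage from 13.12 at e15.5, and Mdk, which fell by 0.56 per stage with the smallest error among them (SE 0.03, adjusted p = 0.000126). Capn6 fell by 0.61 per stage and the embryonic globin Hbb-y by 0.64, the latter from 12.25 at e15.5 to 7.06 at e18.5. The 12 largest falls also held Hdc, Cma1, Cpa3, Fcer1g, Stfa1 and Sspn, and Actc1, a striated muscle actin, fell by 0.82 per stage (SE 0.23, adjusted p = 0.0242). Sspn, Fcer1g and Stfa1 had their largest drop from P2 to P5. They went from 11.15 to 6.77, from 10.26 to 6.82 and from 10.48 to 7.11, so their slopes need not reflect a steady change. The fall of Actc1 was not gradual. Its level was 14.12 at e15.5 and 7.48 at e18.5, rose again at P0 and was 7.11 at P2. The skeletal muscle markers described below were likewise high on the e15.5 and P0 arrays, so this slope need not reflect a steady change with stage.

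**Figure D1:**
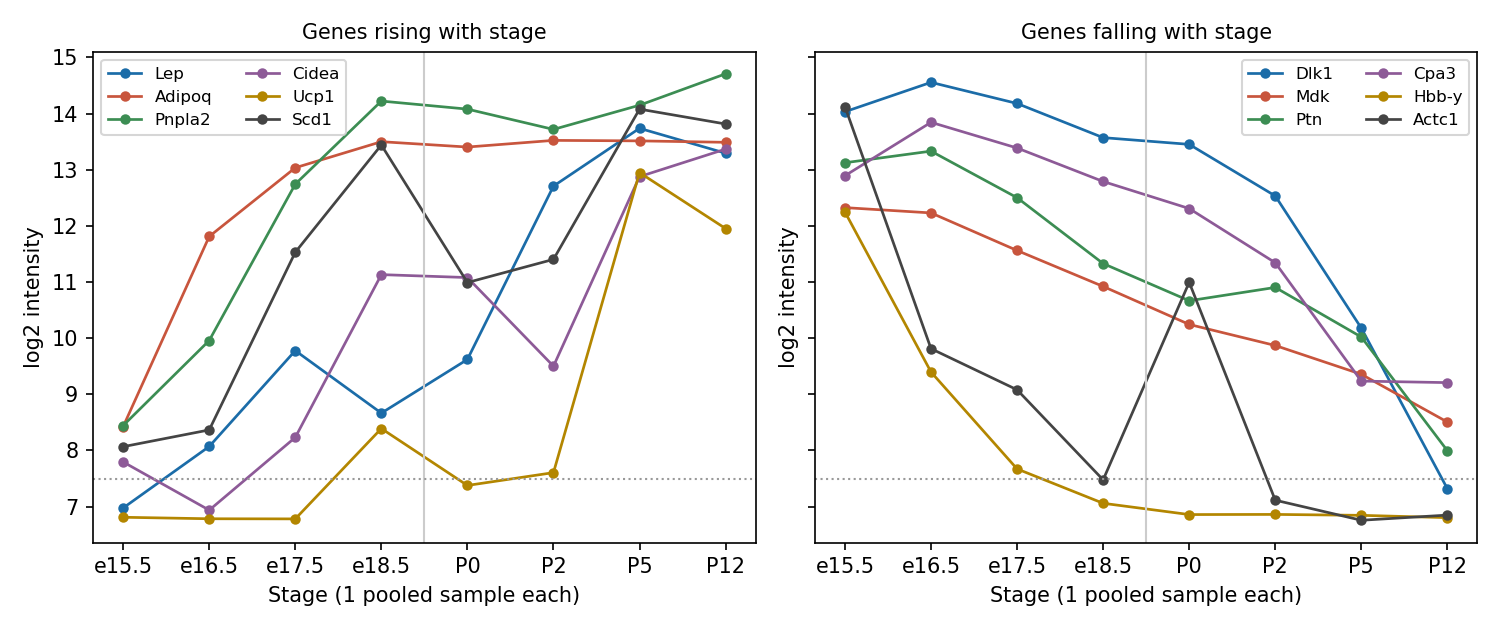
Log2 intensity (vertical axis) of 6 rising and 6 falling genes at the 8 stages (horizontal axis, 1 pooled sample per point). Lep runs from 6.98 to 13.29 and Dlk1 from 14.03 to 7.32; the dotted line marks the 7.5 minimum and the grey line birth.

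Of the 30 tested members of the list of adipocyte lipid storage and adipokine genes, 21 rose and 0 fell (23 and 0 adjusted over the list alone), and camera gave an adjusted p = 1.94e-09. The call was lost with adjusted p = 0.721 with an estimated correlation. The mean level of the list went from 8.27 at e15.5 to 10.85 at e18.5 and 11.55 at P12. Adiponectin, Adipoq, rose by 0.54 per stage (SE 0.17, adjusted p = 0.0358), with most of the gain between e15.5 (8.43) and e17.5 (13.04) and a level of 13.40 to 13.52 from e18.5 on. Mgll, the monoglyceride lipase, rose by 0.63 per stage and Angptl4 by 0.52. The named Fabp4 probe stayed between 6.78 and 7.23 and was not tested, nor was Retn, whose highest value was 7.65.

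Among the 31 tested transcription regulators of adipogenesis 9 rose and 4 fell (9 and 4 adjusted over the list alone), and the list as a whole did not pass (adjusted p = 0.193). Cebpa rose by 0.24 per stage (SE 0.03, adjusted p = 0.00213) and Cebpb by 0.18 (SE 0.05, adjusted p = 0.0304). Klf9 had the steepest rise, 0.40 per stage, and Gata2, a brake on adipogenesis, fell by 0.26. Pparg, the central regulator of fat cell differentiation, was 9.09 at e15.5, 12.11 at e18.5 and 11.53 at P12, a slope of 0.24 (SE 0.11) that did not pass (adjusted p = 0.118). Ets2 ranged from 10.70 to 11.35 and Zfp423 from 7.17 to 7.62 on its tested probe without passing (adjusted p = 0.398 and 0.391).

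All 18 tested genes of fatty acid oxidation rose (18 adjusted over the list alone; camera adjusted p = 9.68e-11, and adjusted p = 0.721 with an estimated correlation), with slopes from 0.20 for Acot2 to 0.47 for Acadvl. The mean level of the list was 9.42 at e15.5, 11.08 at e18.5 and 11.99 at P12. Of 33 tested subunits of the mitochondrial respiratory chain, 26 rose and 0 fell (28 and 1 adjusted over the list alone; adjusted p = 1.03e-08, and adjusted p = 0.721 with an estimated correlation). Their slopes were small, with a mean of 0.13 per stage, the largest being Sdhc at 0.26 and Cox5a at 0.23. In de novo lipogenesis 8 of 17 members rose and 0 fell (8 and 0 adjusted over the list alone; adjusted p = 0.00449, adjusted p = 0.721 with an estimated correlation and 0.0586 by fry), led by Scd1, Thrsp (0.62 per stage) and Mlxipl (0.39). That list was higher at e18.5 (mean 10.71) than at P0 (9.69), and did not pass with the muscle (adjusted p = 0.0575) or the epidermal (adjusted p = 0.0761) marker mean as a covariate.

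Of the 11 tested brown fat genes 8 were higher at both P5 and P12 than on any earlier array; Ppargc1a and Ppargc1b were highest at e18.5 (9.33 and 9.46) and Ebf2 at e16.5 (9.32). Ucp1, the uncoupling protein of brown fat, stood between 6.78 and 8.39 through P2 and at 12.95 at P5 and 11.95 at P12 (slope 0.81, SE 0.21, adjusted p = 0.0161). Cidea rose by 0.86, Cox7a1 by 0.73, Cox8b by 0.66 and Cpt1b by 0.44 per stage, so that 5 of 11 tested members rose and 0 fell (5 and 0 adjusted over the list alone). Fabp3 was 9.56 at e15.5, 9.55 at P0 and 12.95 at P12, and did not pass (adjusted p = 0.126). Cox8b was likewise higher at e15.5 (10.50) than at e16.5 (7.37), and the mean of the skeletal muscle markers was 12.16 and 8.67 on these arrays. The list passed with an adjusted p = 0.0105, and had an adjusted p = 0.721 with an estimated correlation. It did not pass without the P12 array (adjusted p = 0.0558) or without P5 and P12 (0.398).

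Proliferation genes fell. All 26 tested cell cycle genes fell (26 adjusted over the list alone; adjusted p = 4.18e-11, and adjusted p = 0.721 with an estimated correlation), and the mean of the list went from 9.76 at e15.5 and 9.95 at e16.5 to 8.28 at P0 and 7.96 at P12. Top2a, a DNA topoisomerase, fell by 0.44 per stage, Birc5 by 0.42, Prc1 by 0.40 and Cdk1, the mitotic kinase, by 0.38. Imprinted growth genes went both ways. Of 12 tested, 5 fell (Dlk1, Cdkn1c, Grb10, Igf2r and Peg3) and Nnat rose; adjusted over the list alone, 6 fell and 1 rose. Cdkn1c, an inhibitor of cyclin-dependent kinases, fell by 0.53 per stage (SE 0.08, adjusted p = 0.00225), from 14.97 to 11.19, and the growth factor receptor adaptor Grb10 by 0.38. Igf2 stayed at 14.66 or more through P2, then was 13.90 at P5 and 10.21 at P12, a slope of -0.44 that did not pass (adjusted p = 0.0666). The imprinted list passed with an adjusted p = 0.0169, and had an adjusted p = 0.721 with an estimated correlation.

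In the list of fibrillar collagens and matrix 10 of 28 members fell and 0 rose (8 and 0 adjusted over the list alone; adjusted p = 0.0169, adjusted p = 0.743 with an estimated correlation and 0.0586 by fry). Col1a2 fell by 0.35 per stage, Lox, the collagen cross-linking oxidase, by 0.30, and Col1a1 by 0.22, while Sparc (13.73 at e15.5, 14.15 at P12) and Dcn (13.37 and 13.40) did not pass. Without the P12 array the list had an adjusted p = 0.0723. Of 23 progenitor and mesenchyme genes 6 fell and 0 rose, among them Twist2, which fell by 0.22 per stage, and Twist1, which fell by 0.20, and Pdgfra was 10.73 at e15.5 and 11.05 at P12 (list adjusted p = 0.209). Of 11 tested Wnt signalling genes 5 fell, Ccn4 and Fzd2 most, and Fzd4 rose (0.0909, and 0.0114 by fry). The remaining process lists did not pass either. In cholesterol synthesis Insig1 rose and 2 of 16 members fell (0 and 2 adjusted over the list alone; 0.747), in glycolysis 3 of 13 fell, Slc2a1, Gapdh and Tpi1 (0.156), and in the basement membrane 2 of 15 rose and 3 fell (0.726). Of 14 limb and body-wall patterning genes 2 fell (0 adjusted over the list alone; 0.6), and of 13 immediate early and stress genes 2 rose, Dusp1 and Egr2 (1 adjusted over the list alone; 0.641).

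**Figure D2:**
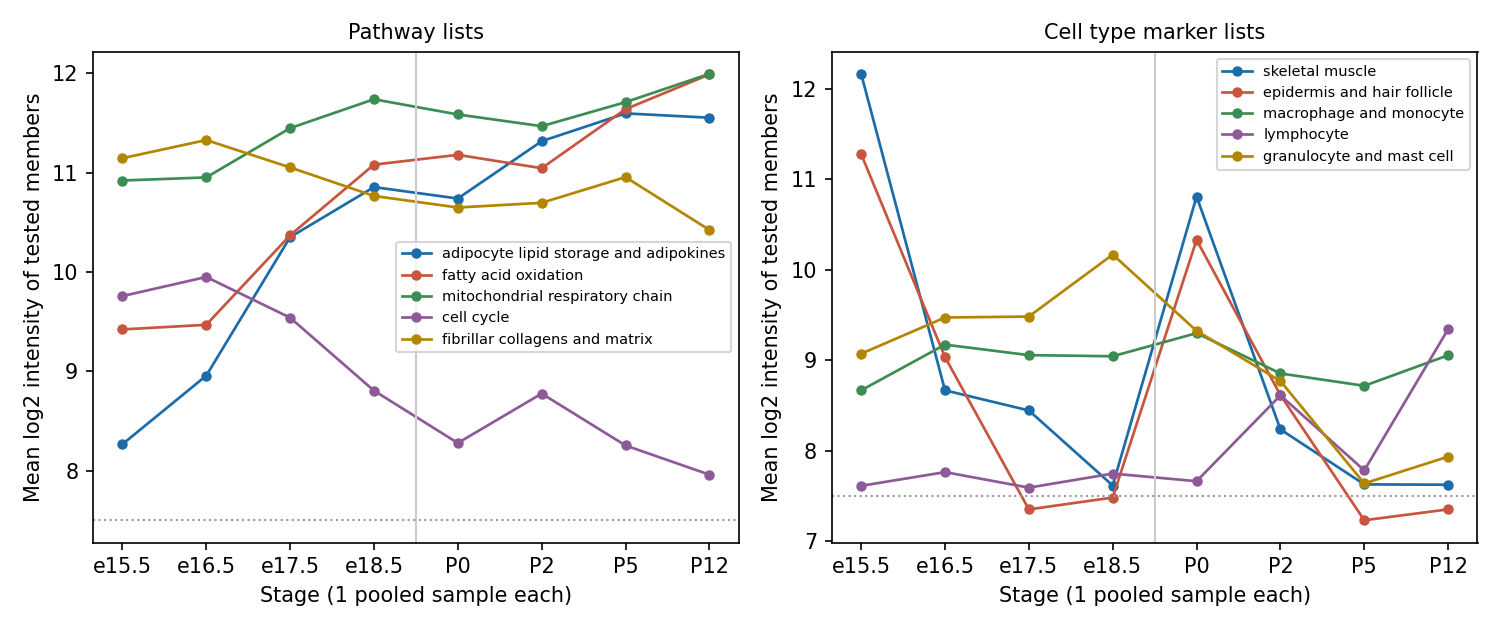
Mean log2 intensity over the tested members of 5 process lists (left) and 5 cell type marker lists (right) at the 8 stages, 1 pooled sample per point; the dotted line marks the 7.5 minimum and the grey line birth. The fatty acid oxidation list runs from 9.42 to 11.99 and the cell cycle list from 9.76 to 7.96, while the muscle list stands at 12.16 at e15.5 and 10.81 at P0 and at 8.67 or below on the other 6 arrays.

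Markers of other tissues were not spread evenly over the arrays. The 20 tested skeletal muscle markers averaged 12.16 at e15.5 and 10.81 at P0, against 7.62 at e18.5 and 8.24 at P2. The 14 tested epidermal markers averaged 11.28 at e15.5 and 10.33 at P0, and 7.48 and 8.61 at e18.5 and P2. Their mean was 9.03 at e16.5, against 7.35 at e17.5, 7.23 at P5 and 7.35 at P12. Epidermal signal was thus also raised, to a lesser degree, at e16.5 and P2. Krt10 was 13.18 at e16.5 and 11.79 at P2. Myh8, a developmental myosin, was 14.93 at e15.5, 7.63 at e18.5, 14.87 at P0 and 6.98 at P5, and Krt14, a keratin of the basal epidermis, was 13.56, 8.79, 12.89 and 6.97. No member of either list rose or fell over stage (0 adjusted over the list alone). The muscle list as a set passed (adjusted p = 0.0243, adjusted p = 0.79 with an estimated correlation and 0.237 by fry) and the epidermal list did not (adjusted p = 0.0708). With the muscle mean as a covariate 793 genes rose and 1100 fell over stage, and with the epidermal mean 766 and 1029.

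Of the mast cell genes Cma1, a chymase, fell by 0.68 per stage, Cpa3, a carboxypeptidase, fell by 0.66, and Hdc, the histamine-forming enzyme, fell by 0.80, the last from 13.51 at e15.5 to 9.26 at P12. Hdc is in no list; of the 13 granulocyte and mast cell markers 3 fell, Cma1, Cpa3 and Tpsb2, and 0 rose (list adjusted p = 0.134), and the mast cell protease Mcpt4 did not pass (adjusted p = 0.355). Of 15 lymphocyte markers 6 rose and 0 fell (7 and 0 adjusted over the list alone; adjusted p = 0.0114, adjusted p = 0.743 with an estimated correlation and 0.108 by fry). Cd74, the invariant chain, rose by 0.45 per stage, and H2-Ab1, a class II antigen, also by 0.45. The mean of the lymphocyte list did not rise steadily: it was 7.66 at P0, 8.61 at P2, 7.78 at P5 and 9.34 at P12. The lymph node gene Glycam1 was 7.46, 9.04, 8.01 and 12.33 on the same arrays. Cd3g was 8.65 at P2, 7.20 at P5 and 9.66 at P12, and Cd8b1, another T cell gene, did not pass (adjusted p = 0.0539). Of 11 erythroid markers 6 fell and 0 rose (6 and 1 adjusted over the list alone; 0.0909, and 0.0357 by fry), Hbb-y and the adult globin Hbb-bt most. Hbb-bt was 10.06 at P2 and 7.33 at P5, whereas Hbb-b2, another adult beta globin of the list, was 6.90 and 9.33 and did not pass (adjusted p = 0.0543). Of 17 macrophage markers 4 rose, Cd163 and Lyz2 most, and 2 fell (0.418). Fcer1g, the Fc receptor gamma chain, was 10.26 at P2 and 6.82 at P5, whereas Tyrobp, also of this list, was 7.99 and 7.82.

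Vascular and nerve markers showed single genes that changed within lists that did not pass. Of 22 endothelial markers 2 rose, Mmrn2 and Vwf, and 2 fell, Pdpn and Lyve1 (0.462). Of 12 pericyte and smooth muscle markers Rgs5 rose by 0.44 per stage, from 8.27 at P2 to 10.41 at P5, and Smtn fell (0.908). Of 5 Schwann cell and nerve markers the myelin gene Mbp rose by 0.41 and Gap43 fell by 0.22 (0.455). Of 3 cartilage and bone markers 2 fell, Sox9 and Col9a2 (0.134, and 0.0114 by fry). Of 4 luminal and glandular epithelial markers Esr1 rose (0.734; the mean and median slopes were below 0 and the set test pointed up), and the milk protein gene Csn3 was 9.35, 8.56 and 9.18 at e18.5, P0 and P2 and at most 7.01 elsewhere. Lists of 2 tested members were not tested as sets: of the melanocyte markers Gpnmb rose and Ednrb did not pass, and of the sex-linked transcripts Eif2s3y fell and Xist did not pass. Adjusted over the list alone, Ednrb and Xist passed too, both upward.

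The comparison of the 4 embryonic with the 4 postnatal arrays asked which genes differed between the periods, and cannot separate a step at birth from a steady change with stage. Slc48a1, a heme transporter, was the one gene past the threshold. It averaged 8.92 (SD 0.14, n = 4) before and 10.03 (SD 0.08, n = 4) after birth, a difference of 1.11 log2 (SE 0.10, limma adjusted p = 0.0246), and was higher on each of the 4 postnatal arrays than on any embryonic one. Genes with larger differences, such as Lep (difference 3.97 log2, adjusted p = 0.0578), Hdc (-3.61, 0.0538) and Nnat (3.53, 0.0564), did not pass. With limma, 1 gene was higher and 0 were lower at an adjusted p of 0.05, and 1081 and 1368 at an unadjusted p of 0.05. The count rested on single arrays. Without e18.5, 805 genes were higher and 1075 lower, without P0 9 and 3, and without any 1 of the other 6 stages 0 and 0. Some other settings moved the count too. Array weights gave 734 higher and 1064 lower, the epidermal mean as a covariate 390 and 434, and the muscle mean 104 and 103. A level of 7.5 on all 8 arrays gave 118 and 159, whereas no intensity filter gave 3 and 1.

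With camera 9 of 27 lists passed, and 0 with an estimated correlation. Higher after birth were fatty acid oxidation (18 of 18 members higher and 18 past the threshold adjusted over the list alone, mean difference 1.38 log2, adjusted p = 4.74e-08), adipocyte lipid storage (29 of 30 higher and 15 past it, 1.69, adjusted p = 1.24e-07), the respiratory chain (0 of 33 past it, 0.42, adjusted p = 2.95e-05), brown fat (0 of 11, 1.43, adjusted p = 0.034) and lymphocyte markers (0 of 15, 0.67, adjusted p = 0.0201), each with adjusted p = 0.785 with an estimated correlation. Lower were the cell cycle (26 of 26 past the threshold adjusted over the list alone, mean difference -1.20, adjusted p = 9.47e-13), glycolysis (4 of 13, -0.46, adjusted p = 0.0205), fibrillar collagens (2 of 28, -0.39, adjusted p = 0.0205) and granulocyte and mast cell markers (4 of 13, -1.13, adjusted p = 0.0236), each again with adjusted p = 0.785 with an estimated correlation. At e18.5 and P0 themselves the list means were 11.08 and 11.18 (fatty acid oxidation), 10.85 and 10.74 (adipocyte) and 11.74 and 11.58 (respiratory chain). They were 9.40 and 9.03 (brown fat), 7.75 and 7.66 (lymphocyte) and 8.80 and 8.28 (cell cycle). The other called lists stood at 10.66 and 10.44 (glycolysis), 10.76 and 10.65 (fibrillar collagens) and 10.17 and 9.32 (granulocyte and mast cell). By fry 1 list passed, cartilage and bone (adjusted p = 0.0216).

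The curvature test asked which genes lay above, or below, a straight line in the middle of the series. Cidec, a lipid droplet protein, was 6.89 at e15.5, between 10.85 and 11.94 from e17.5 to P2 and 9.26 at P12 (coefficient 4.32, SE 0.57, adjusted p = 0.0323, probe ILMN_1222679). Trf, transferrin, was 9.33, 14.46 at e18.5 and 11.76 at P12 (4.19, SE 0.45), Adig, adipogenin, was 7.22, 12.80 at P0 and 11.61 (3.43, SE 0.46), and Gpat3, a triglyceride synthesis enzyme, was 7.01, 11.32 at P2 and 10.04 (3.04, SE 0.39). Dlk1 also passed, with 14.56 at e16.5 and a fall that steepened after P2. Lowest in the middle were Acot11, a thioesterase (7.95 at e15.5, 7.05 at e18.5 and 8.98 at P12), Cyria, Drp2 and Tmem25. Hbb-y also passed with a negative coefficient, but its level dropped early and then lay at the floor. In all 39 genes had a positive and 13 a negative coefficient at an adjusted p of 0.05, and 828 and 705 at an unadjusted p of 0.05. These counts include genes such as Dlk1 and Hbb-y, which have no peak or low point in the middle. The counts were 40 and 15 without P5, 21 and 1 without P12, 2 and 0 without P0, and 0 and 0 without any 1 of the other 5 stages.

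Differences between neighbouring stages show when the changes fell; they rest on 1 array each side and have no replicate check. From e15.5 to e16.5, 94 features were 2-fold or more higher and 324 lower. The total of 418 became 136 with 7.5 required on all 8 arrays and 696 with the lowest value subtracted. Totals of the other steps moved with these settings too. Adipoq was 10.4-fold and the mast cell protease Mcpt4 8.70-fold higher at e16.5, and the muscle genes Actn2, Tnnc2 and Tnnc1 were 28.2-, 26.8- and 22.8-fold lower, on a step over which the muscle marker mean went from 12.16 to 8.67. From e16.5 to e17.5, 166 were higher and 44 lower, with Scd1 8.96-fold, Cidec 7.31-fold and Chchd10 7.07-fold higher and the epidermal genes Krt10 and Krtdap 15.7- and 5.24-fold lower. From e17.5 to e18.5, 156 were higher and 34 lower. Irf4, a transcription factor of immune cells and adipocytes, was 15.8-fold higher at e18.5, Cstdc4 9.10-fold and Retnlg 7.72-fold, and the muscle genes Myh8 and Acta1 were 9.14- and 5.64-fold lower and G0s2, an inhibitor of lipolysis, 3.76-fold lower.

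From e18.5 to P0, 141 features were higher and 128 lower. Among genes at 7.5 or more on both arrays, the 3 largest increases were the muscle and epidermal genes Myh8 (151-fold), Acta1 (58.3-fold) and Krt10 (41.6-fold), on the array where both marker lists stood above their neighbours, and Serpina3n was 7.92-fold and Orm1 6.25-fold lower, as was Irf4, at 11.58 and 7.54. From P0 to P2, 63 were higher and 148 lower, with Sncg 25.9-fold, Nnat 14.3-fold and Lep 8.5-fold higher and Myh8 29.0-fold and Mylpf 20.6-fold lower. From P2 to P5, 113 were higher and 160 lower. Ucp1 was 40.6-fold, Retnla 20.0-fold and Cidea 10.4-fold higher at P5, and Mcpt4 was 8.35-fold, Krt10 7.19-fold and the ribosomal protein gene Rpl29 6.49-fold lower. From P5 to P12, 105 were higher and 55 lower, with the lymph node gene Glycam1 20.0-fold and Cyp2e1 12.2-fold higher and the imprinted genes Igf2 and Mest 13.0- and 6.93-fold lower. Between e15.5 and P12, 881 features were higher and 919 lower.

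**Figure D3:**
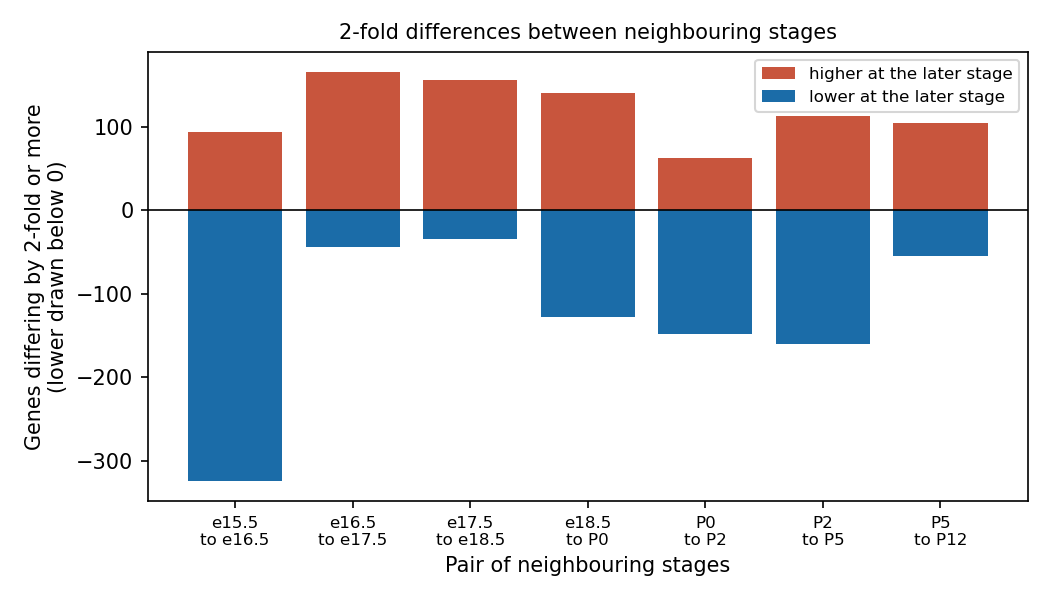
Number of features (vertical axis) that differed by 2-fold or more between neighbouring stages (horizontal axis), with those higher at the later stage above 0 and those lower below 0. The bars run from 63 to 166 features higher and from 34 to 324 lower; there are no replicates and no error bars.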

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

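Every test of the 3 patterns weighed here was chosen after the result had been seen; the comparison of each array with its period was fixed before the data were examined. In 54 sets of 4 arrays (27 gene lists in each of the 2 periods), 1 array stood apart. The endothelial marker list had a mean of 9.39 at e15.5, against 9.88 or more on the other embryonic arrays, and this gap was 0.897 of the whole range, above Dixon's 95% limit for 4 samples. Chance puts about 1 in 20 such sets above the limit. No explanation was tested.

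Epidermal and skeletal muscle transcripts were high on the e15.5 and P0 arrays. The epidermal mean was also raised, to a lesser degree, at e16.5 (9.03) and P2 (8.61), against at most 7.48 at e17.5, e18.5, P5 and P12. A steady change with stage was argued against, since the median member was 2.08 log2 higher at P0 than on the higher of its neighbours (quartiles 1.27 and 2.81). So was a P0 array that is really a much earlier stage: genes with a steady trend, marker lists left out, placed it at stage order 5.0, with an SD of 0.847 for the placement errors of the other 7 arrays. Skin and muscle tissue in the e15.5 and P0 pools and a change in the tissue itself at these ages stay open and cannot be told apart. That 94.1% of the members (32 of 34) had e15.5 and P0 as their 2 highest arrays restates the pattern and favours neither.

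With at most 1 log2 of range within each set of arrays and a gap of at least 1.5, 20 probes switched between P2 and P5, 13 off and 7 on, against at most 4 for any other pair of arrays (27 against 16 with a range of 1.5, and 88 against 69 with a gap of 1 as well), while 42 set the single e15.5 array apart. Arl3 and Ercc5 each had a bright second probe that moved by less than 0.5 log2 (-0.30 and 0.16, mean -0.069), which argues against lower abundance of every transcript of these genes. A sequence difference under single probes between the P5 and P12 mice and the younger ones could explain these. But the second probe was level in 50% of the genes that had a bright one (2 of 4), and in Rpl29 and Ctsc it moved too. Both Rpl29 probes are among the 20, so its second probe was itself picked for switching. For 13 named genes, among them Atf4, Tomm22, Sspn, Retnla, H2-T10 and Hbb-b2, no bright second probe existed. A permutation test of neighbouring pairs (2, against 0.649 in random sets) gave p = 0.128. These tests cannot tell sequence and abundance apart for the 13 genes. Hbb-b2 was 6.90 at P2 and 9.33 at P5, whereas Hbb-bt, another adult beta globin, went the other way, at 10.06 and 7.33. What this opposite movement reflects was not tested. The 8.5 minimum for a bright second probe was set after the moves of dimmer ones had been seen (with those of Fgfr1op2 and Apex1 counted, at 7.85 and 7.62, 4 of 6 were level), and age stays open and untested.

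Of 11 tested brown fat genes 8 were higher at both P5 and P12 than on any earlier array, and Ppargc1a, Ppargc1b and Ebf2 were not. Skeletal muscle, which shares Cox8b, Cox7a1, Fabp3 and Cpt1b with brown fat, was argued against as the source, since its markers were lower there than at e17.5 (median -0.52 log2, 16 of 20 below 0). Classical brown fat in these pools could be another source; its markers Zic1, Lhx8 and Prdm16 had a highest value of 7.20 on any array, near the floor, and probes this dim cannot decide it. Thermogenic change within the depot with age stays open and untested.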

How the results depend on the processing

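The other intensity minimums, the subtraction of the lowest value, the centring on always bright probes and the fits without pairs of stages were chosen after seeing the data; the other alternatives were planned. Over the settings with 1 probe per gene 563 to 1459 features rose and 529 to 1649 fell, against 1812 and 1892 probes of all tested singly, and 0 were called in the opposite direction. Centring shifted the arrays by -0.05 to 0.03 log2. Over the named genes and alternatives, a trend call was lost 244 times, gained 78 times and turned 1 time, and 3003 results were unchanged in call. Of the losses, 56 came without P5 and P12, 27 with each of the muscle and epidermal means, and 25 without P12. Causes were not tested unless the setting itself gives them, such as fewer arrays or genes.

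With 1 stage left out, in turn, 891 to 1458 genes rose and 999 to 1600 fell, both lowest without P12. Genes higher after birth ran from 0 to 805 and lower from 0 to 1075, both highest without e18.5. Genes peaking ran from 0 to 40 and lowest in the middle from 0 to 15. The brown fat list ran from an adjusted p of 0.00184 to 0.0558 and the collagen list from 0.000875 to 0.0723, both highest without P12.

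Without P5 and P12, 563 genes rose, 529 fell, 0 were higher after birth, and 0 peaked or were lowest in the middle; the brown fat list had an adjusted p of 0.398, glycolysis 0.0422, and the slope of Cyria turned from 0.21 to -0.0031. Without e15.5 and P0, 4 genes were higher and 2 lower after birth, and 0 peaked or were lowest in the middle. With time in days 903 rose and 986 fell.

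With the epidermal marker mean as a covariate 766 rose, 390 were higher and 434 lower after birth, 65 peaked and 31 were lowest in the middle, and lipogenesis had an adjusted p of 0.0761. With the muscle mean 793 rose, 104 were higher and 103 lower, 21 were lowest in the middle, lipogenesis had 0.0575 and the muscle list turned direction (0.563). Array weights gave 734 higher and 1064 lower, and 0 peaking or lowest in the middle.

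With no intensity filter 3 genes were higher and 1 lower, 0 peaked or were lowest in the middle, and the progenitor list passed (0.0492). With 7.5 on all 8 arrays 118 were higher, 159 lower and 8 lowest in the middle, the brown fat list had 0.288, and the steps in order gave 136, 110, 101, 90, 59, 124 and 81 genes, with 1064 between e15.5 and P12. With a minimum of 8 the Wnt list passed (0.0265). All probes singly gave 1 gene lower after birth. With the lowest value subtracted 2 were lower, 63 peaked, and the steps gave 696, 346, 365, 479, 371, 536 and 325, with 2764 between e15.5 and P12. A 3-fold limit gave 207, 62, 54, 115, 91, 95 and 53, and 832.

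With an estimated correlation 0 lists passed in either comparison. The adjusted p was 0.721 for adipocyte lipid storage, brown fat, the cell cycle, lipogenesis, fatty acid oxidation, imprinted genes and the respiratory chain, and 0.743 for collagens. With fry 9 lists passed for the trend and 1 for birth (cartilage and bone, 0.0216). For the trend it ended the calls of lipogenesis (0.0586), collagens (0.0586), lymphocyte markers (0.108) and muscle markers (0.237), and added Wnt (0.0114), erythroid markers (0.0357) and cartilage and bone (0.0114).

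Not run were the alternatives that need the unused columns: no background correction, median centring without quantile normalization, another offset and the detection filters. The processed values, planned as an alternative, are the ones used throughout. No paired analysis was possible because each stage had 1 pool. What signal over background limits cannot be read from the deposited values; dim probes have compressed differences.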

Other observations

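The counts under other orders and splits were planned before the data were examined; the e18.5, P2 and sex-linked values were picked after they had been seen. Of 100 orders of the 8 arrays, 1, the real one, gave as many genes in the trend test (2905, highest other 1687). A random order of these arrays is thus unlikely to give the count. Each stage is a single pool, so differences between pools that happen to follow stage are not excluded. In the curvature test 2 of 100 orders, the real one included, gave as many (real 52, highest other 291). This met the limit that had been fixed beforehand. Because another order gave more genes than the real one, chance is still not taken as excluded for the curvature count. The order with 291 genes put P12 among the embryonic stages and e15.5 last; a count several times the real one points to a structure of the samples, and what it is was not tested. Of the 35 splits into 4 and 4 arrays, 3, the real one included, gave as many genes as the embryonic and postnatal split (real 1, highest other 1). Every split gave 0 or 1 gene, so this count can hardly tell splits apart. Chance cannot be excluded there, and the count does not decide it.

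The e18.5 array had 30 features at least 2-fold above every other array; the counts were 148 at e15.5, 10 at P0, 3 at P5, 31 at P12 and 0 on the other 3. They included Irf4 (11.58, at most 8.26 elsewhere), the neutrophil genes S100a9 (11.36), S100a8 (13.00) and Retnlg (10.46), the metallothionein Mt1 (14.63), Nfil3 (11.65), Xdh (10.61) and the coactivator Ppargc1a (9.33). Cd8b1, a T cell gene, was 9.27 at P2, 7.15 at P5 and 10.32 at P12. The Y-linked Eif2s3y was 7.93 at e15.5 and at most 6.80 from P2 on. Xist was 8.91 at P5 and 8.70 at P12, and at most 7.81 before. With 1 pool per stage, any difference in sex make-up between the pools cannot be told apart from stage in the fits. The unnamed probe ILMN_2835423 was 7.26 at e15.5, 11.61 at e16.5 and at least 14.62 from e17.5 on.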
